A study of Mus musculus with 2 samples.

How the data were processed

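Small RNAs of bone marrow-derived dendritic cells were measured in 2 libraries, 1 from a pellet that held the nuclei and 1 from the cytoplasmic fraction. Per the labels' protocols, bone marrow cells were grown for 7 days in medium with fetal bovine serum, GM-CSF and IL-4 and stimulated with lipopolysaccharide (LPS). Cells were swollen in a buffer with the mild detergent NP40 and spun, RNA of both fractions was purified with a miRNA isolation kit, and libraries followed Illumina's small RNA protocol. The dose and duration of the stimulation are not given in the sources used here.

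The authors' deposited table lists 538100 distinct sequences of 18 to 39 nt with a value for each library in RPM, reads scaled to a common library total. Per the submitters' processing notes, CASAVA was used and the genome build was mm10. The adapter trimming, length limits, alignment and any filter are not given in the sources used here, so it is open whether sequences without a genomic match had been kept. The deposited columns carry abbreviations that differ only in the last letter, and the columns were taken as nuclear (N) and cytoplasmic (C) on that letter.

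In both columns 100% of the values above 0 were whole multiples of the value of 1 read within a tolerance of 0.1 read. The value of 1 read was 0.500 RPM in the nuclear and 0.490 RPM in the cytoplasmic library. Whole reads were recovered from this, giving 2000019 nuclear and 2041383 cytoplasmic reads. These are the reads listed, and the total sequenced is not known. The libraries were of similar depth.

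No small RNA names come with the sequences. Every sequence was matched to the transcripts of GENCODE vM21 (GRCm38, the assembly also called mm10) on the sense strand over its full length without a mismatch. Sequences with no such match were matched to small RNA and ribosomal RNA transcripts after removal of up to 3 nt at the 3′ end, with at least 18 nt left, since mature small RNAs often carry added 3′ nucleotides. Of 408 nuclear tRNA loci in the RefSeq table (GRCm38.p6), 10 lay inside an annotated exon, which gave their sequence. These were matched with CCA added at the 3′ end, and other tRNA genes and the genome outside transcripts were not matched here. Exact matches took 52.8% of nuclear and 67.8% of cytoplasmic reads, and matches after 3′ removal a further 7.57% and 13.0%. The same sequences read backwards matched for 0.101% and 0.0234% of reads, which gives the level of chance matches.

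Each sequence entered a single class in a fixed order, so that a sequence of both a small RNA and a longer transcript counted as the small RNA. Sequences in more than 10 long genes were called repeat-like and named to no gene. A miRNA is an arm (5p or 3p) of an annotated hairpin, with all its 3′ and 5′ variants summed. Sequences shared by miRNAs formed a joint entry where neither had more reads of its own. Other shared miRNA sequences counted in the miRNA class but under no single miRNA. A gene with reads in exons and in an intron that an annotated transcript retains gave separate entries. Names follow GENCODE, in which some miRNA letters are dropped. In the other classes paralogs and near-identical copies share reads, and the copy named is the one with most reads.

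Small RNAs with at least 50 reads over both libraries (892) were compared. The level ratio was the nuclear RPM over the cytoplasmic RPM, also given as a log2 ratio with a pseudocount of 0.5 reads, which understates the change of small RNAs with few reads. Exact (Clopper-Pearson) 95% intervals were computed for shares and, conditional on the reads of both libraries, for ratios. A small RNA was called higher or lower when the log2 ratio reached 2-fold and the interval excluded 1. The interval alone excluded 1 for 429 small RNAs higher and 229 lower in the nuclear library, and it included 1 for 234. With 1 library in each group, a count model such as edgeR's quasi-likelihood test had no residual degrees of freedom and could not be fitted, so no p-value is given. Where a small RNA had no read in a library, the fold was computed against a floor of 3 reads in that library.

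Before the data were examined, 16 lists were fixed: LPS-induced miRNAs, myeloid and haematopoietic miRNAs, the let-7 family, the miR-17~92 and paralogous clusters, miRNAs described in nuclei elsewhere, mirtrons and other Drosha-independent miRNAs, the miR-29 family, miRNAs of other cell types (erythroid, lymphoid, epithelial, stromal or smooth muscle, endothelial, and liver, muscle or neural), nuclear RNA classes, cytoplasmic RNA classes and ribosomal RNA fragments. A list's median log2 ratio was placed among 10000 random lists of the same size, drawn from miRNAs (or, for the classes, all small RNAs) of similar abundance. Lists with under 3 measured members were given values only. The rule for the small RNAs named, also fixed before, took the 10 with the largest and the 10 with the smallest ratio whose interval excluded 1, the 10 most abundant in each library, and the measured members of the lists. Other names were chosen after their values were seen, which is stated beside them.

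The alternatives fixed beforehand were scaling by edgeR's TMM factors, by the median of ratios and to the miRNA total; no minimum of reads and a minimum of 500; a pseudocount of 5; the most abundant sequence of each small RNA alone; sequences with a single annotation; lengths of 18 to 25 nt; and distinct sequences in place of reads. Matches over the full length alone were added after the data were seen. Relative to RPM, the scalings subtract 0.26 (TMM), 0.49 (median of ratios) and -0.91 (miRNA total) from every log2 ratio.

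The comparison was tested on simulated reads for the 892 small RNAs, with 200 of them changed. At 8-fold and at 4-fold, 100% of the changed ones were called, and at 2-fold, which is the threshold itself, 56.5%. Of the 692 unchanged ones, 3 were called in the simulation at 2-fold, 3 at 4-fold and 1 at 8-fold. Intervals held the true ratio for 95.1% of small RNAs at 2-fold. The simulated reads held counting error alone, which the intervals assume, with as many small RNAs raised as lowered. The simulation therefore checks the computation and does not cover spread between replicates or the choice of scaling. In the test of the list step, 2.50% of 200 random lists of 20 miRNAs fell under the 5th percentile, and 100% did after their log2 ratios were lowered by 1. All of 500 planted pieces were matched at their place, and 0 pieces with 1 changed base. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, were used.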

Results

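Small RNAs of 18 to 39 nt were sequenced from dendritic cells grown from the bone marrow of C57BL/6 mice and stimulated with LPS, a component of the outer membrane of Gram-negative bacteria that these sentinel cells of innate immunity detect. GM-CSF and IL-4, the cytokines in the culture, drive bone marrow precursors towards dendritic cells. RNA of the pellet that held the nuclei gave the nuclear library, and RNA of the remaining fraction gave the cytoplasmic library, with 1 library of each. The design asks which small RNAs are enriched in the nuclei of such cells. The nuclear library held 2000019 reads of 400087 distinct sequences and the cytoplasmic library 2041383 reads of 169208 distinct sequences, and 31195 sequences were in both. With 1 library in each group, no difference has a replicate check. The ratios compare these 2 libraries, not the conditions in general, and intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

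The first comparison asked how RNA classes divide between the fractions. miRNAs made up 39.7% of nuclear and 74.7% of cytoplasmic reads, a share 1.88-fold higher in the cytoplasmic library (95% interval 1.87 to 1.88). Fragments of small nucleolar RNAs (snoRNAs), which guide the modification of ribosomal RNA in the nucleolus, made up 9.35% of nuclear and 0.298% of cytoplasmic reads, 31.4-fold higher in the nuclear library (30.6 to 32.2). Small Cajal body RNAs (scaRNAs), which guide the modification of spliceosomal RNAs, were 15.0-fold higher (12.3 to 18.3). Spliceosomal and related small nuclear RNAs (snRNAs) were 2.54-fold higher in the nuclear library (2.45 to 2.63).

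Fragments of introns that annotated transcripts retain made up 0.924% of nuclear and 0.120% of cytoplasmic reads, 7.69-fold higher in the nuclear library (7.38 to 8.03). Fragments of long non-coding RNA exons were 5.66-fold higher (5.42 to 5.91), and fragments of mRNA exons were higher as well, with a log2 ratio of 0.59. Ribosomal RNA fragments with a match made up 2.83% of nuclear and 1.64% of cytoplasmic reads. Ribosomal RNA sequences also lay among the reads without a match. Both shares therefore cover only part of the ribosomal RNA, and the ratio for all of it was not measured. Mitochondrial tRNA fragments were 2.82-fold higher in the cytoplasmic library (2.65 to 3.01), and fragments of the few cytosolic tRNAs with a known sequence 3.68-fold higher (3.33 to 4.07). Mitochondrial ribosomal RNA was 1.19-fold higher in the cytoplasmic library (1.14 to 1.25). Under scaling to the miRNA total its genes changed sign, to log2 ratios of 0.55 (mt-Rnr1) and 0.75 (mt-Rnr2).

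Not every class known from the cytoplasm lay there. Y RNA fragments were 3.36-fold higher in the nuclear library (2.84 to 3.99) and 7SL RNA, the RNA of the signal recognition particle, 1.75-fold higher (1.48 to 2.08). Vault RNA did not differ detectably at this depth, at 1.07-fold (0.906 to 1.27). 7SK RNA, a nuclear regulator of transcription elongation, was 1.63-fold higher in the nuclear library, but its most abundant sequence alone was lower. RNase P and MRP RNA had 50 nuclear and 36 cytoplasmic reads, and its ratio of 1.42 had an interval that held 1 (0.905 to 2.24). With sequences of a single annotation only, its direction turned. Shares of a library depend on each other, so a class with fewer reads raises the share of all others. Reads without a match were 39.6% of the nuclear and 19.1% of the cytoplasmic library and entered no comparison by name.

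**Figure D1:**
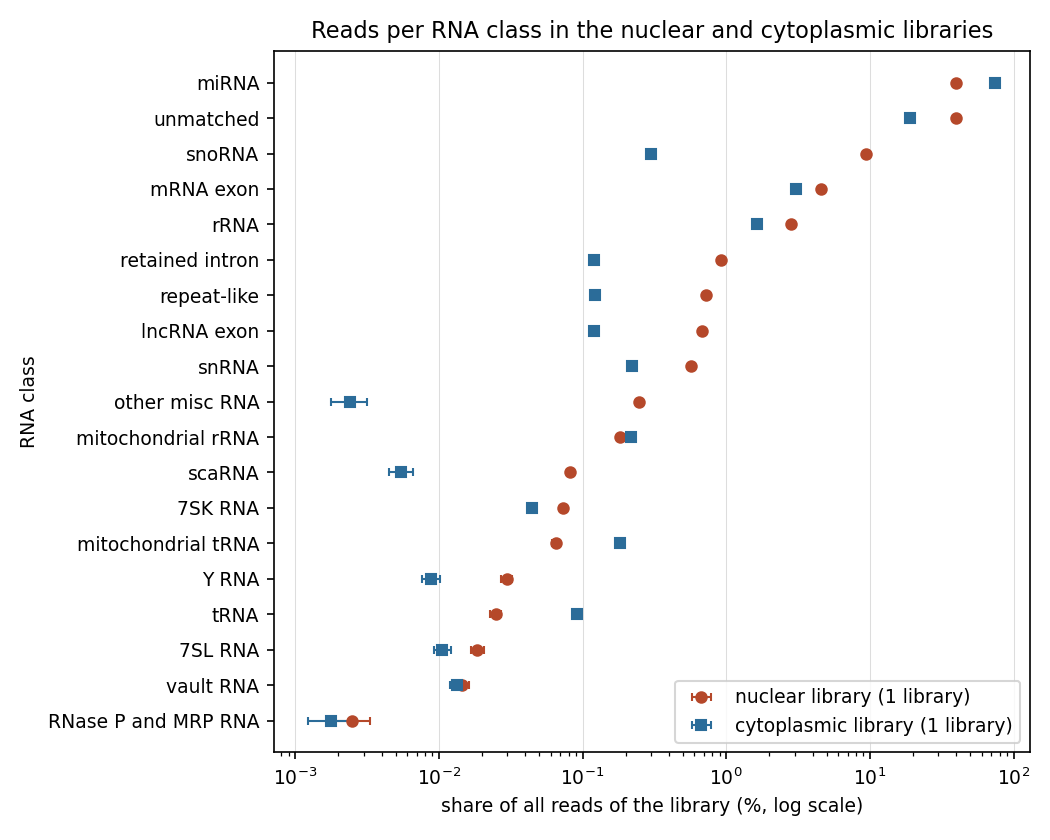
Share of all reads (%, log scale) of each RNA class in the nuclear library (circles) and the cytoplasmic library (squares), 1 library each, with exact 95% binomial intervals. miRNAs made up 39.7% of nuclear and 74.7% of cytoplasmic reads, and snoRNAs 9.35% and 0.298%.

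The second comparison asked which single small RNAs were higher in either library. Of 892 small RNAs measured, 346 were higher and 111 lower in the nuclear library, 435 were neither, and the median log2 ratio was 0.51. The split depended on the scaling, with 302 higher and 164 lower under TMM factors, 270 and 230 under the median of ratios, and 539 and 28 under scaling to the miRNA total. Of 119 snoRNAs, 117 were higher in the nuclear library and 0 lower, with a median log2 ratio of 4.82, or 4.69 with the 6 that had no cytoplasmic read at their bound. Under the other scalings 116 to 119 snoRNAs were higher and 0 lower. All 4 scaRNAs were higher, as were 26 of 34 retained introns, 20 of 27 long non-coding RNAs and 6 of 11 snRNAs.

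The largest ratio belonged to Snord37, a C/D box snoRNA in an intron of the elongation factor gene Eef2 (GRCm38 chromosome 10, positions 81178950 to 81179013, plus strand), with 2782 nuclear and 4 cytoplasmic reads, 710-fold higher in the nuclear library (277 to 2607). Gm27733, annotated in an exon of Xist, the RNA that silences an X chromosome (chromosome X, 103461218 to 103461285, minus strand), followed with 4795 and 16 reads, 306-fold higher (188 to 536). Gm26224 and Mir5117, typed as snoRNAs, lie within the snoRNA host gene Gas5 on chromosome 1. They had 767 against 3 reads (261-fold, 89.0 to 1268) and 1081 against 6 reads (184-fold, 84.2 to 502). Exons of all annotated transcripts of a gene were pooled, those that retain introns included. A small RNA placed in an exon here may thus lie in an intron of other transcripts. Rnu73b, in an intron of the ribosomal protein gene Rps3a1, had a single cytoplasmic read (261-fold, 46.5 to 10360). Snord111, overlapping an exon of the splicing factor gene Sf3b3, had 383 against 2 reads (195-fold, 53.7 to 1620). Snord93, in an intron of 2700038G22Rik, had 107 nuclear and no cytoplasmic reads, at least 36.4-fold higher against a floor of 3 reads (lower end of the 95% interval 29.1).

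The same group held fragments from longer genes. Non-coding transcripts of Rabggtb, a gene that also holds Snord45b and Snord45c, had 124 nuclear and no cytoplasmic reads, at least 42.2-fold higher against the floor of 3 reads (lower end of the 95% interval 33.8). Retained introns of Rpl6, a ribosomal protein gene, and St8sia4, a sialyltransferase gene, had 82 and 78 nuclear reads and no cytoplasmic read, at least 27.9-fold and 26.5-fold higher against that floor (lower ends 22.2 and 21.1). Rpl6 likewise holds a small RNA gene, Gm26205. Snord14c, within the chaperone gene Hspa8, was the most abundant snoRNA with 70030 nuclear and 1256 cytoplasmic reads, 56.9-fold higher (53.8 to 60.2).

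**Figure D2:**
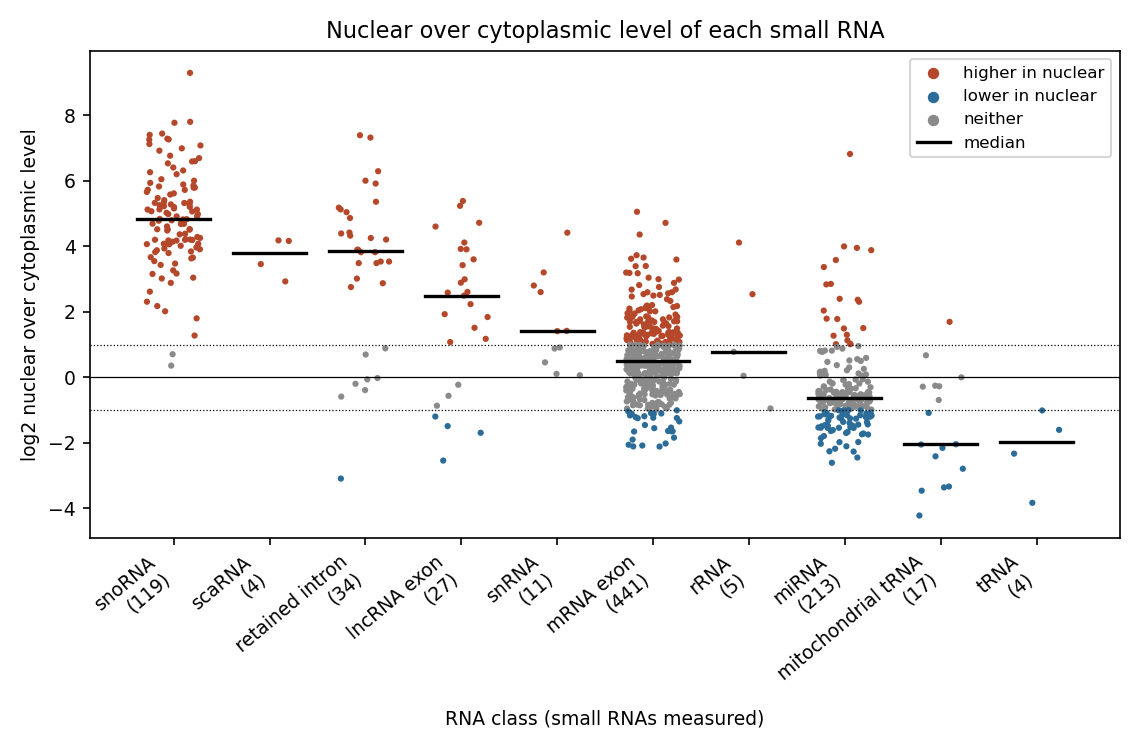
Log2 ratio of nuclear over cytoplasmic level of each small RNA (points), by RNA class with the number measured, with the class median (black bar) and dotted lines at 2-fold. Of 119 snoRNAs 117 lie above the upper line with a call, while the miRNA median of -0.63 lies below 0, on the other side under scaling to the miRNA total (0.28).

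Nuclear RNA classes, fixed as a check of the fractions, had 138 measured members, of which 129 were higher in the nuclear library and 0 lower, with a median log2 ratio of 4.53 (4.50 at the bounds; 5.43 under the miRNA total) and a position above all of 10000 random lists. The long non-coding RNAs Neat1 and Malat1, which build paraspeckles and locate to nuclear speckles, were higher at 15.2-fold (12.2 to 19.2) and 6.02-fold (5.33 to 6.82). U3 snoRNA (Rnu3b1) was 15.7-fold higher (14.7 to 16.8), U6 (Rnu6) 9.22-fold (8.20 to 10.4), and U7 (Rnu7), which acts in histone mRNA processing, 21.9-fold (13.7 to 37.4). U2 (Rnu2-10) had a ratio of 1.37 (1.31 to 1.44), under the 2-fold threshold, and U5 (Rnu5g) had 47 nuclear and 46 cytoplasmic reads. The single most abundant sequence of Malat1 had the opposite direction, with a log2 ratio of -1.84 against 2.59 for all its sequences.

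Cytoplasmic RNA classes had 27 measured members, of which 14 were lower in the nuclear library and 2 higher, with a median log2 ratio of -1.01, below all of 10000 random lists. Under scaling to the miRNA total the median was -0.10, with 6 higher and 11 lower. Among the 17 mitochondrial tRNAs 10 were lower, among them mt-Td with 11 nuclear and 219 cytoplasmic reads, 19.5-fold higher in the cytoplasmic library (10.7 to 39.7), and mt-Ts2 with 154 and 1743 reads, 11.1-fold (9.40 to 13.2). mt-Ta (10.8-fold, 5.64 to 23.1), mt-Tf (11.3-fold, 4.11 to 43.1) and mt-Ty (7.21-fold, 3.83 to 15.0) were also among the most cytoplasmic, while mt-Tp was 3.27-fold higher in the nuclear library (2.14 to 5.15). The arginine tRNA locus n-TRtcg5 (chromosome 7, 79466419 to 79466491, plus strand) had 9 and 138 reads, 15.0-fold higher in the cytoplasmic library (7.69 to 33.5). All 4 measured tRNAs were lower in the nuclear library, 2 of them also under scaling to the miRNA total. The Y RNA Rny3 was 5.16-fold higher in the nuclear library (4.08 to 6.61). The mitochondrial ribosomal RNAs mt-Rnr2 (2017 nuclear and 2307 cytoplasmic reads) and mt-Rnr1 (1650 and 2158) were neither higher nor lower. The nuclear library thus also held RNA from outside the nucleus.

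Other entries high in the cytoplasmic library were named for a long transcript but led by tRNA-like sequences. The entry under Adarb2 had 4 nuclear and 154 cytoplasmic reads, 37.7-fold higher (14.4 to 140), of which 4 and 130 were GTCCCTGTTCGGGCGCCA, which has the CCA end of a tRNA. The entry under Cep112it was 6.04-fold higher (3.26 to 12.2), led by TCCCGGGTTTCGGCACCA (2 and 66 reads), with the same end, and that under an intron of Ttyh1 8.76-fold (5.37 to 15.2), led by TTAATCTCAGGGTCGTGGGT, a stretch found in lysine tRNAs. Most cytosolic tRNA genes were not matched here, so origin from Adarb2, Cep112it or Ttyh1 is not shown. miR-664-5p, whose hairpin overlaps the snoRNA gene Snora36b in an intron of Rab3gap2, was 6.23-fold higher in the cytoplasmic library (3.96 to 10.3), opposite to the snoRNAs. Ribosomal RNA fragments had 5 measured members, 2 higher and 0 lower in the nuclear library. Their median log2 ratio was 0.78 (percentile 69.9, and 1.69 under the miRNA total). Without a minimum of reads this median turned to -1.37. Ribosomal RNA reads without a match entered neither the median nor the percentile, so both describe only part of the ribosomal RNA. The 18S-related entry Gm42418 was among the most abundant in the nuclear library (51946 and 30943 reads, 1.71-fold, 1.69 to 1.74), although its single most abundant sequence had the opposite direction (731 and 1737 reads).

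miRNAs leaned to the cytoplasmic library. Of 213 measured, 61 were lower and 22 higher in the nuclear library, with a median log2 ratio of -0.63 that changed sign to 0.28 under scaling to the miRNA total. The split was 18 higher and 90 lower under TMM factors, 16 and 131 under the median of ratios, and 43 and 9 under the miRNA total. let-7f-5p, let-7a-5p and let-7c-5p were the most abundant small RNAs of the nuclear library, with log2 ratios of -0.71, -0.67 and -0.55. Since that library also held mitochondrial RNA, a high level there does not by itself place a miRNA in the nucleus. miR-21a-5p, an oncogenic and inflammation-linked miRNA, was the most abundant of the cytoplasmic library and 3.95-fold lower in the nuclear library (54762 and 220925 reads, 3.92 to 3.99). miR-140-3p was 3.06-fold lower (3.01 to 3.11).

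LPS-induced miRNAs, the list closest to the treatment, had 20 measured members, of which 11 were lower and 0 higher in the nuclear library. Their median log2 ratio was -1.05, lower than in all but 1.46% of random lists of miRNAs, and it was -0.14 under scaling to the miRNA total, where 2 were higher and 1 lower. miR-146b-5p (log2 ratio -1.54) and miR-146a (named miR-146-5p in the annotation, 502 nuclear and 1447 cytoplasmic reads), which dampen Toll-like receptor signalling, were lower, as were miR-221-3p (-1.55), miR-222-3p (-1.17), miR-99b-5p (-1.40), miR-9-5p and both arms of miR-21a. miR-155-5p, a promoter of inflammatory responses in myeloid cells, stood apart at 1.39-fold nuclear over cytoplasmic (1.35 to 1.42), with 12219 and 9002 reads, although its log2 ratio of 0.47 became -0.02 under the median of ratios. miR-212-3p had a ratio of 1.11 (0.915 to 1.35). No unstimulated cells were analysed here, so these values do not show a response to LPS.

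Myeloid and haematopoietic miRNAs had 21 members, 7 lower and 0 higher, with a median log2 ratio of -0.74 (percentile 38.9) that turned to 0.17 under scaling to the miRNA total. miR-342-3p (-1.64), the joint entry of miR-27a-3p and miR-27b-3p (-1.25) and miR-511-3p (-1.19) were lower, and the myeloid miR-223-3p had a log2 ratio of -0.61. The separate entry of miR-27a-3p (-0.57) was neither higher nor lower. The let-7 family had 10 members, 0 lower and 1 higher, with a median of -0.61 (percentile 84.1; 0.30 under the miRNA total), and the higher member was let-7d-3p, a passenger arm, at 2.83-fold (1.99 to 4.09). The miR-17~92 and paralogous clusters had 11 members, 3 lower and 0 higher, with a median of -0.61 (percentile 64.0; 0.30 under the miRNA total), and miR-93-5p and miR-25-3p were lower (-1.25 and -1.11). The miR-29 family had 3 members and no call, with a median of -0.76 (percentile 48.5; 0.14 under the miRNA total).

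miRNAs described in nuclei elsewhere had 12 members, 0 higher and 5 lower in the nuclear library, with a median log2 ratio of -0.62 (percentile 76.9; 0.29 under the miRNA total). The nearest to equal levels were miR-744-5p (1.13-fold nuclear over cytoplasmic, 1.08 to 1.18), miR-15a-5p (1.04-fold, 0.952 to 1.13) and miR-16-5p (0.953-fold, 0.922 to 0.985), and miR-29b-3p had a ratio of 0.706 (0.656 to 0.760). Mirtrons and other Drosha-independent miRNAs had 6 members, 2 higher and 0 lower, with a median of 0.47 (percentile 99.5) that became -0.02 under the median of ratios and 1.38 under the miRNA total. The higher ones were miR-6236-5p (7.28-fold, 5.45 to 9.90) and miR-5107-5p (5.01-fold, 3.43 to 7.52). Reads of miR-6236-5p were spread over 79 sequences, with 16.0% of reads at the commonest 5′ end, unlike a processed miRNA arm. Those of miR-5107-5p lay in 57 sequences, with 69.7% at the commonest 5′ end. The list median and percentile include both entries.

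**Figure D3:**
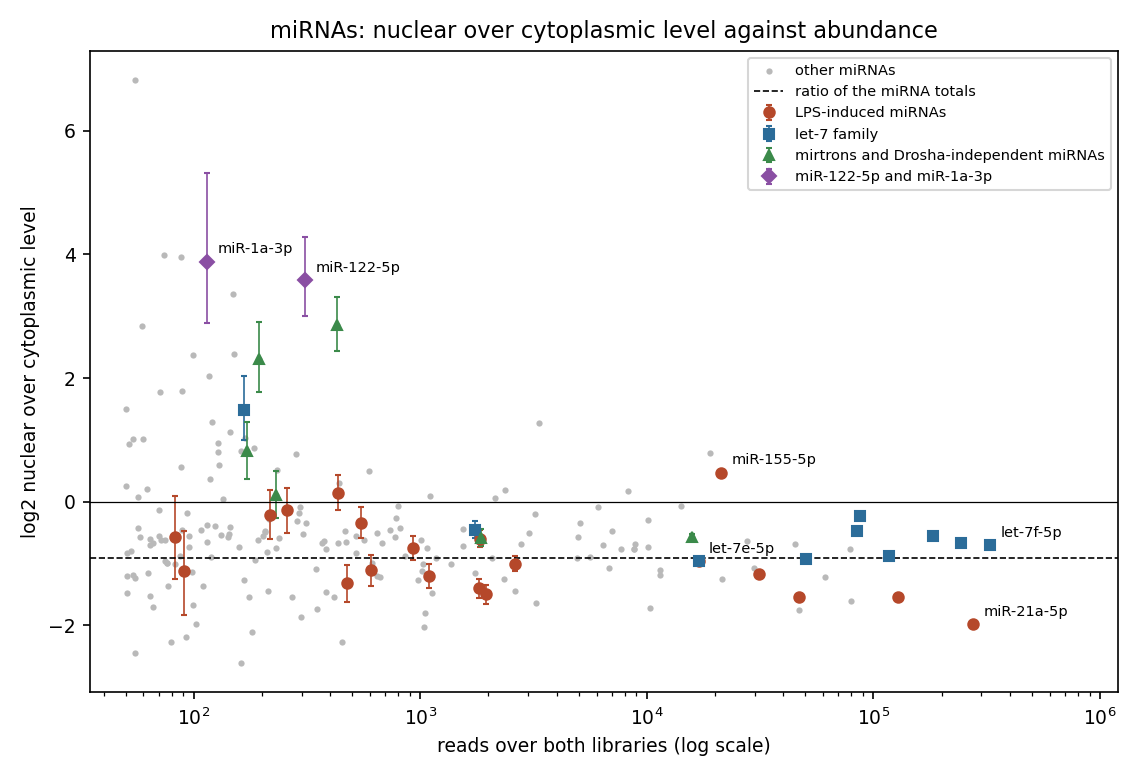
Log2 ratio of nuclear over cytoplasmic level of each of 213 miRNAs against its reads over both libraries (log scale), with members of 4 fixed lists marked and their exact 95% intervals. The dashed line is the ratio of the miRNA totals (-0.91), which becomes 0 under scaling to the miRNA total; let-7e-5p is a member of 2 of the lists.

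miRNAs of other cell types were mostly scarce, but not all. The stromal joint entry of miR-199a-3p and miR-199b-3p had 562 nuclear and 540 cytoplasmic reads, against 392 and 612 of the myeloid miR-223-3p. No erythroid or endothelial miRNA reached 50 reads, and miR-451a, the main miRNA of red cells, had 0 nuclear and 2 cytoplasmic reads. miR-122-5p, the main miRNA of hepatocytes, had 287 nuclear and 24 cytoplasmic reads, 12.2-fold higher in the nuclear library (8.04 to 19.4), and the muscle miRNA miR-1a-3p had 108 and 7 reads, 15.7-fold higher (7.39 to 40.1). Of 3 stromal or smooth muscle entries, miR-143-3p was higher (2.20-fold, 1.53 to 3.19) with RPM and not under TMM factors or the median of ratios, and the list median of 0.93 (1.84 under the miRNA total) lay at percentile 95.2. The 3 epithelial entries of the miR-200 family had a median of -0.81 (percentile 22.1; 0.10 under the miRNA total), with miR-200a-3p lower in the nuclear library (-2.27). The lymphoid list had 2 measured members, miR-181a-5p (-0.48) and miR-181a-3p (-2.45), which myeloid cells also express.

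mRNA fragments gave 441 of the measured small RNAs, 142 higher and 29 lower in the nuclear library. That split was 104 and 51 under TMM factors, 79 and 73 under the median of ratios, and 299 and 5 under the miRNA total. Their median log2 ratio was 0.51, as over all 892 small RNAs, a median that these 441 largely set themselves. The most abundant, Lars2, a mitochondrial leucyl-tRNA synthetase gene known to hold a sequence related to 28S ribosomal RNA, had 9223 and 9159 reads, 96.9% of them within 300 nt of its transcript. It was singled out after its values were seen.

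The third comparison asked whether sequence lengths differ. Both libraries peaked at 22 nt, the usual miRNA length, with 27.6% of nuclear and 38.8% of cytoplasmic reads. Sequences of 18 to 20 nt made up 30.3% of nuclear reads (95% interval 30.2 to 30.4) and 18.9% of cytoplasmic reads (18.9 to 19.0). Sequences of 26 to 32 nt, the range of piRNAs and of longer snoRNA fragments, made up 2.49% (2.47 to 2.51) and 1.11% (1.09 to 1.12). The few reads of 33 to 39 nt went the other way, with 0.0560% and 0.0918%, 1.64-fold higher in the cytoplasmic library (1.52 to 1.77). Counted over distinct sequences in place of reads, 22 nt held 14.3% of nuclear and 15.7% of cytoplasmic sequences.

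**Figure D4:**
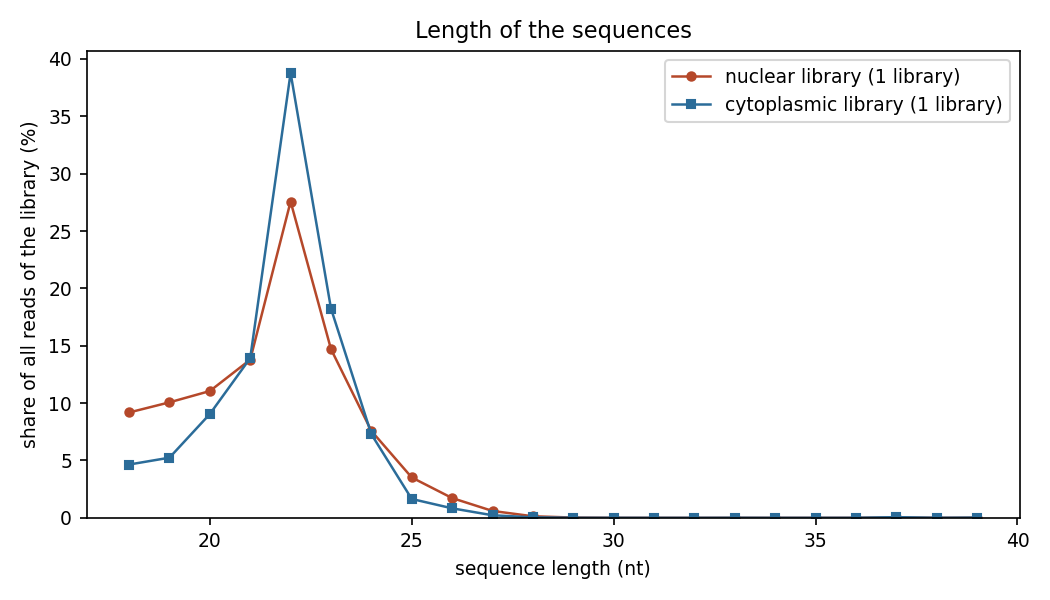
Share of all reads (%) of each sequence length (nt) in the nuclear library (circles) and the cytoplasmic library (squares), 1 library each. At 22 nt the shares were 27.6% and 38.8%, and lengths of 18 to 20 nt had 30.3% and 18.9%.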

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

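Some signal lay in reads outside the named comparisons, which entered no class. All tests in this part were chosen after the results were seen. Reads with no transcript match made up 39.6% of the nuclear and 19.1% of the cytoplasmic library. Unmatched reads ending in CCA, the triplet added to the 3′ end of mature tRNAs, made up 0.509% of the nuclear and 1.42% of the cytoplasmic library. Unmatched reads with a C-box motif (RUGAUGA, with R for A or G), a mark of C/D snoRNAs, made up 1.001% of the nuclear and 0.0408% of the cytoplasmic library.

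The excess of CCA ends in the cytoplasmic library came from 2 lengths, 18 nt (1554 nuclear and 9333 cytoplasmic reads, 5.88-fold higher) and 22 nt (2103 and 15802 reads, 7.36-fold), whereas CCA-ending reads of other lengths were 1.74-fold higher in the nuclear library. Different read lengths in the libraries are argued against for 18 and 22 nt, lengths picked for their excess, since the lower of their ratios of shares within reads of the same length was 5.23, while the ratio at other lengths ran from 0.133 (23 nt) to 1.504 (19 nt). A few abundant sequences do not carry it alone, though they carry much of it, since the lower ratio without the 10 most abundant sequences of each length was 1.84. The 3′ ends of mature tRNAs remain, as 93.6% of the 22-nt reads start with TCA or TCG, as in the T loop of tRNAs, against 2.02% of 22-nt unmatched reads with other ends, so these reads may be tRNA fragments of fixed length that lie mainly in the cytoplasm. Examples are TCGTTTCCGGCTCGAAGGACCA (106 and 3745 reads) and its 18-nt 3′ part TTCCGGCTCGAAGGACCA (35 and 431 reads).

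miR-122-5p (287 and 24 reads) and miR-1a-3p (108 and 7 reads) were higher in the nuclear library, against the direction of most miRNAs. Chance fragments of other RNAs are argued against, because at least 92.9% of the reads of either start at a single 5′ end. Cells of liver or muscle, or their RNA from another source, cannot be told apart from expression in these cells. Such a source could be the serum of the culture medium, in which miRNAs of this list are also abundant, or neighbouring samples. Of the other listed miRNAs of these tissues, miR-206-3p had the most nuclear reads, 31 against 11 cytoplasmic reads, and miR-133a-3p had 2 and 0. With no second library, a source shared by all nuclear preparations stays open too.

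LPS-induced miRNAs lay low among miRNAs in the ratio of nuclear to cytoplasmic level, at percentile 1.46. A single hairpin does not carry the list, since the highest percentile with 1 of its 14 hairpins left out was 3.68, without miR-21a. GC content is not excluded, as the list lay at percentile 6.48 once a linear GC trend was removed. The trend was weak (0.15 log2 units for 10 points of GC), and the median GC was 45.5% in the list and 47.6% in the other miRNAs. Recent transcription after LPS, which could place more of a miRNA in the cytoplasm or in the nucleus, was not tested, because no unstimulated cells were analysed here.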

How the results depend on the processing

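The full-length matching was chosen after the data were seen, and the other alternatives before. Of the 261 named small RNAs, 12 changed sign with their most abundant sequence alone, among them 2 with a call, Malat1 (-1.84) and mt-Tc (0.95). The other 10 were neither higher nor lower: Gm42418 (-1.22), Rn7sk (-0.79), Rnu12 (-2.003), Gm23444 (-0.12), Gm23568, Rnu5g, mt-Tl1 (0.53), mt-Tm, mt-Ts1 and mt-Tv. Full-length matches changed the sign of Rnu5g, Rpph1 and mt-Tv, all near 0, and the scalings that of 10 (TMM), 13 (median of ratios) and 48 (miRNA total). The cause was not tested for any change below unless the construction gives it. Depth limits small RNAs near 50 reads, where a 2-fold change can miss the threshold. No paired analysis was possible because each group has 1 library.

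Counts of calls followed the scaling by construction, since each scaling shifts all ratios alike. The median of ratios gave 230 small RNAs and 131 miRNAs lower in the nuclear library. The miRNA total gave 539 higher and 28 lower, with 43 miRNAs higher and 9 lower. Without a minimum of reads, small RNAs higher in nuclear level were 2419 and those lower 245, with 45 miRNAs higher and 99 lower and 203 snoRNAs higher, because more small RNAs were compared. With at least 500 reads there were 52 higher and 35 lower, because fewer were compared. Among entries annotated as miRNAs 1 was higher (miR-6240-5p, 2344 nuclear and 992 cytoplasmic reads) and 31 lower, and 40 snoRNAs were higher. Whether the reads of miR-6240-5p come from a miRNA hairpin or from another RNA was not tested.

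Under TMM factors the list medians shifted to -1.32 (LPS-induced miRNAs), -1.28 (cytoplasmic classes), -0.87 (let-7), -1.03 (miR-29), -0.89 (miRNAs described in nuclei), -1.004 (myeloid), 4.26 (nuclear classes) and 0.51 (ribosomal RNA). Without a minimum of reads they were -0.51 (let-7), -0.54 (miR-29), -0.54 (miRNAs described in nuclei), 3.30 (nuclear classes) and -1.56 (epithelial), and that of ribosomal RNA fragments reversed from 0.78 to -1.37. A pseudocount of 5 gave 3.89 for nuclear classes.

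Class log2 ratios kept their sign with single annotations at 0.32 (7SK), 1.45 (7SL), 0.61 (mRNA exons), -0.90 (miRNA), 5.08 (other misc RNA), 0.83 (rRNA), 2.35 (repeat-like), 3.03 (retained introns), 0.97 (snRNA) and 4.54 (snoRNA), while the class log2 ratio, RNase P and MRP RNA, moved from 0.50 to -1.94. Lengths of 18 to 25 nt gave 2.06 (Y RNA), 0.64 (mRNA exons), -0.89 (miRNA), 0.82 (rRNA) and 5.02 (class log2 ratio, snoRNA). Full-length matches gave -0.92 (miRNA), -1.37 (mitochondrial tRNA), 0.82 (rRNA) and 5.02 (snoRNA). By distinct sequences, 22 nt held 14.3% (nuclear) and 15.7% (cytoplasmic).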

Other observations

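Some mRNA fragments were grouped by gene name after the values were seen, which tests no division by kind of gene, and over all 441 mRNAs 142 were higher and 29 lower in the nuclear library. Of 5 immediate early and stress transcription factor mRNAs, Jun, Fos, Ier5 and Atf4 were higher in the nuclear library, and Junb was neither. Log2 ratios were 3.19 (Jun), 2.88 (Fos) and 2.76 (Ier5). Cxcl2, an LPS-responsive chemokine mRNA, was higher as well (3.40) while Ccl5, Ccl6, Ccl22 and Cxcl3 were neither higher nor lower. Of 6 mitochondrially encoded mRNAs, 4 were lower, among them mt-Atp6 (-2.09) and mt-Co3 (-1.19). mRNAs of abundant myeloid proteins lay on the cytoplasmic side, with Lyz2 (lysozyme) at -2.06, Chil3 at -2.11, Arg1 (arginase) at -2.02 and Ctss (cathepsin S) at -1.65. Of 5 cathepsin mRNAs 2 were lower and 3 neither, and of 17 ribosomal protein mRNAs 5 were lower, 2 higher and 10 neither. Fragments of Mir155hg, the host transcript of miR-155, had 90 nuclear and 3 cytoplasmic reads (30.6-fold, 10.1 to 151), against 1.39-fold for the mature miR-155-5p. Scaling to the miRNA total adds 0.91 to each of these log2 ratios.

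miRNA 3′ ends differed little between the fractions. An unmatched 3′ A ended 9.41% of nuclear and 8.62% of cytoplasmic miRNA reads, an unmatched 3′ T 2.42% and 2.61%, and any unmatched tail of up to 3 nt 17.9% and 17.2%. Among unmatched sequences, GACTCTTAGCGGTGGATCACTCGG, from the 5′ part of 5.8S ribosomal RNA, had 7843 nuclear and 466 cytoplasmic reads (17.2-fold, 15.6 to 18.9), while overlapping sequences had opposite directions, GGCGGGTGTTGACGCGATG with 9705 and 2104 and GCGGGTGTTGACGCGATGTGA with 2157 and 9715.

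Of the tests in the remaining paragraphs, that on miRNA 5′ ends was fixed before its result was seen, and the others were chosen after. A hypothesis was that annotated miRNAs higher in the nuclear library are fragments of longer RNAs with no fixed 5′ end, for which the median share of reads at the commonest 5′ end would lie at least 20 points below that of the other miRNAs. It lay 19.1 points below (79.4% for the 22 higher miRNAs and 98.4% for 191 others), short of that bound and above the 10 points set for rejection, so the test did not decide. let-7d-3p (97.6%) and miR-143-3p (98.6%) had fixed ends, and miR-6236-5p (16.0%) and miR-8114-5p (53.7%) did not. Among the others, the joint entries Gm47287/Gm47304/Gm47305 (20.9%) and Gm47295/Gm47299 (27.6%) had no fixed end either. Annotation as a miRNA thus does not by itself show a processed miRNA.

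Exon and retained-intron fragments of the same gene were compared without a test. In 16 genes with reads in both exons and a retained intron, the median log2 ratio was 0.69 for exons and 4.29 for introns. Cxcl3 (exon -0.31, intron 5.18), Vim (-0.30 and 4.26) and Fth1 (-0.41 and 4.21) had exons near equal and introns high in the nuclear library. Cd74 (-0.30 and -0.07) differed little, and Wnk1 (1.07 and -0.02) had the opposite order.

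Another hypothesis was that unmatched reads with a C-box motif are fragments of C/D snoRNAs outside the transcripts matched. Their level was 24.5-fold higher in the nuclear library (22.9 to 26.3), against 2.32-fold for the motif read backwards, an excess of 10.6-fold. Without the 10 most abundant sequences it was 14.6-fold. CCACCATGATGACGGAAATT had 3102 nuclear reads and 1 cytoplasmic read (3166-fold, 568 to 125096). It is the most abundant Snord37 sequence (CACCATGATGACGGAAATT, 2526 and 4 reads) with 1 more C at the 5′ end, so part of these reads may come from annotated snoRNAs with ends beyond their annotation.

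The last hypothesis concerns a single position of tRNA fragments. Position 4 of the 22-nt tRNA 3′ ends, counted from their 5′ end, is tRNA position 58, an adenosine that is often methylated. Of 3148 reads a single base away from the 3′ ends of 8 tRNA sequences, 98.0% differed at position 4. Without n-TGccc7, the commonest, 82.2% of 304 reads did. These shares leave out 694 reads that matched the ends exactly. Position 4 differed in 6 of the 8, while n-TPtgg2 had A10G alone in 9 reads and n-TRtct4 A5G alone in 6. n-TGccc7 had 34 nuclear and 176 cytoplasmic exact reads (TCGATTCCCGGGCGGCGCACCA) against 367 and 2429 with A4T, and n-TSgct5 had 8 and 98 exact reads against 14 and 87 with A4T and 1 and 28 with A4G. The end shared by n-TSaga9, n-TStga1 and n-TStga2 was mostly exact. It had 17 nuclear and 352 cytoplasmic exact reads against 5 and 54 with A4T and 0 and 21 with A4G. A modified base misread by the reverse transcriptase cannot be told apart from tRNA genes with another base there, which were not matched here, and matching without mismatches may thus have left tRNA fragments among the unmatched reads.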
